A study of Mus musculus with 10 samples.

How the data were processed

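Lenses were dissected from mouse embryos at embryonic day 13.5 (E13.5), and the pair of lenses from each embryo was combined into 1 RNA sample, per the labels' protocols. Total RNA (100 ng) was converted to biotinylated sense-strand cDNA with the Affymetrix whole-transcript assay, which draws its target from the length of a transcript rather than from its 3' end, and each sample was hybridised to 1 array, per the labels' protocols. The submitters' processing notes name GCOS, the Affymetrix scanner software. The table holds 35557 probe sets on 10 arrays, 5 from control embryos and 5 from DicerCN embryos, and the labels describe the 5 samples of each group as independent embryos. No column of per-sample values outside these 10 arrays was present or used.

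The deposited values are taken to be log2 signals: they run from 1.91 to 15.2, and the array medians lie between 6.54 and 6.56. The method by which the authors summarised and normalized the probes is not given in the sources used here, and the log base is read from the range of the values. The near-equal medians and the closely matching distributions show that the arrays had been scaled to one another before deposit, so a change of total RNA per lens cannot be seen in them. Correlations between arrays ran from 0.977 to 0.990, and no pair of arrays held identical values. An array gives no count of molecules, so the number of arrays limits the precision: the median standard error of a gene's log2 change was 0.0986.

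Probe sets were named through the platform annotation of the series. It gave 1 gene symbol for 21789 probe sets, several for 1621 and none for 12147, and the last 2 kinds were left out of the main test. Symbols were matched by gene ID to the RefSeq gene table of assembly GRCm38.p6 for 21698 probe sets, the other 91 kept the platform's symbol, and 0 symbols changed. For 999 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, which left 19938 genes. Among the genes named by rule, the probe sets of Atxn1 differed most in size, at 1.46 and 0.62 on the log2 scale, and the second probe set of Ptbp1 did not pass the test. Near-identical crystallin genes, the gamma crystallins Cryga to Crygf above all, can bind the same probes, so their separate values are uncertain. No coordinates are given, because the build of the array design is not given in the sources used here.

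DicerCN and control arrays were compared with limma (version 3.58.1, R 4.3.3) on the deposited log2 values, with lmFit and eBayes at their default settings, 2-sided, and Benjamini-Hochberg adjustment over all genes. A gene differed when its adjusted p was under 0.05. Changes are DicerCN minus control on the log2 scale, with the standard error (SE) of the fit. Single values were compared by exact 2-sided permutation tests over the 252 ways of parting 10 arrays into 5 and 5, for which the smallest possible p is 0.00794. Gene lists were tested with limma's camera at its preset correlation of 0.01 over 36 lists with at least 5 measured genes, with Benjamini-Hochberg adjustment over the lists. The lists came from general knowledge of the pathways and of reported microRNA targets and not from these samples. Each list was tested again with the correlation between its genes estimated from the data, and with fry, which asks if the genes of a list move 1 way on balance and does not set the list against other genes. For each list the number of calls is also given after adjustment over the list alone. List scores are the mean over members of log2 signal minus the control mean.

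The samples, the main tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The named genes are Dicer1, the 12 largest rises and the 12 largest falls among genes that passed the test with all DicerCN arrays on 1 side of all control arrays (clone, predicted and numbered-locus names and near-identical receptor families left out), and up to 4 members of each list by smallest p. That makes 153 genes, of which 93 passed the test. A few other genes are named and marked as chosen after their values were seen. The genes named for the gene families, and the most abundant markers of retina, macrophages and muscle, were also chosen after their values were seen. The lists comprise the microRNA pathway, reported targets of let-7, the miR-17 family, miR-204, miR-200 with miR-205, and miR-124, p53 targets, apoptosis effectors, crystallins, lens fibre genes, lens epithelium genes, lens transcription factors, G1/S and DNA replication, G2/M and mitosis, cyclin-dependent kinase inhibitors, Wnt, FGF and ERK, BMP and TGF-beta, Notch, epithelial junctions, extracellular matrix, unfolded protein response, heat shock and oxidative stress, interferon response, glycolysis and hypoxia, cholesterol synthesis, imprinted growth genes, noncoding and coding hosts of microRNA precursors, and markers of neural retina, pigment epithelium, periocular mesenchyme, surface ectoderm and cornea, erythroid cells, endothelium and vessels, macrophages and striated muscle.

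The procedure was tested on simulated data: 200 of 19938 genes were shifted in simulated groups of 5 arrays with the means and spreads measured here. The test recovered 64% of 100 genes shifted by 0.5 on the log2 scale and 95% of 100 genes shifted by 1, and 4.22% of its calls were unchanged genes. All 4 lists shifted by 0.4 were found and 0 unchanged lists were called. Simulated genes were independent, which real members of a list are not. The alternatives were quantile normalization, median centring, leaving out the 33.3% of genes with the lowest mean signal, all probe sets, the mean of a gene's probe sets, trend and robust variance, array weights, treat at 1.2-fold, a 1.5-fold minimum, an adjusted p under 0.01, the replicate number as a block, the level of Y-linked genes as a covariate and leaving out each array in turn. An alternative pseudocount was not run because the values are already logarithms. After the data had been seen, the scores of the retina, macrophage and muscle lists were added as covariates, as was a fit without control replicate 4 and DicerCN replicate 5. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.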

Results

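Gene expression was measured in lenses of E13.5 mouse embryos that differed in Dicer, the ribonuclease that cuts microRNA precursors into mature microRNAs. DicerCN embryos carried the Le-Cre transgene, in which the P0 promoter of Pax6 drives Cre recombinase in the surface ectoderm that forms lens and corneal epithelium, and 2 loxP-flanked Dicer alleles. Control embryos carried the same flanked alleles and no Cre. Each group had 5 arrays, each from the lens pair of 1 embryo. The array medians lay between 6.54 and 6.56 on the log2 scale, and the first principal component, with 28.6% of the variance, parted the groups. The median SD of a gene was 0.134 in control and 0.165 in DicerCN lenses.

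The comparison asked which transcripts change in the lens when Dicer is deleted from its precursor. Dicer1 itself had log2 signals of 10.23, 10.01, 10.32, 10.07 and 10.20 in control replicates 1 to 5 and of 10.37, 10.26, 10.19, 10.20 and 10.45 in DicerCN replicates 1 to 5. The groups did not differ in it (0.13 higher in DicerCN lenses, 95% confidence interval −0.05 to 0.31, limma adjusted p = 0.472, exact permutation p = 0.127). The labels do not say which exons were flanked, and a probe set over the whole transcript can lie outside them, so this value does not check the labels.

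In DicerCN lenses 6 of 15 crystallins and 7 of 20 genes of cholesterol synthesis fell and none rose, while 11 of 29 p53 targets and 6 of 22 reported targets of the miR-17 family rose and none fell. As whole lists these were shifted by camera with its preset correlation and not with an estimated one (adjusted p = 0.287, 0.287, 0.223 and 0.287 with an estimated correlation). The steepest fall was that of Crygs, the gene of gamma S crystallin, which was 10.2-fold lower (log2 11.18 ± 0.13 in control and 7.83 ± 0.53 in DicerCN lenses, SD, n = 5 each). Btg2 and Trp53inp1, antiproliferative genes induced by p53, rose 3.30-fold and 2.79-fold. In all, 1303 of 19938 genes (6.54%) differed, of which 511 were higher and 792 lower in DicerCN lenses. The median size of these changes was 0.48 on the log2 scale, and 30 genes rose and 42 fell at least 2-fold. All DicerCN arrays lay on 1 side of all control arrays in 1472 genes (7.38%, against 0.794% by chance), among them 1069 of the genes that differed.

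Among the 12 largest rises, Slc6a15, a transporter of neutral amino acids, rose by 2.28 (SE 0.33, limma adjusted p = 0.00145), with DicerCN arrays spread over an SD of 0.84. Pros1, the gene of protein S, rose by 1.80 (SE 0.18, adjusted p = 0.000153) and Thbs1, the matrix protein thrombospondin 1, by 1.68 (SE 0.25, adjusted p = 0.00171). Pik3r3, a regulatory subunit of phosphoinositide 3-kinase, rose 2.92-fold and Nnat, the imprinted gene of neuronatin, rose 2.84-fold. The others were Prtg (2.77-fold), an immunoglobulin-family receptor of early embryos, Megf10 (2.74-fold), a receptor for engulfment of cells, Atxn1 (2.74-fold), Khdrbs3 (2.60-fold), an RNA-binding protein, and Alox12 (2.59-fold), a lipoxygenase. After Crygs, the largest falls were those of Gcg, the gene of proglucagon (fell by 2.91, SE 0.29, adjusted p = 0.000155), and of Lrtm1, a leucine-rich repeat transmembrane protein (fell by 2.35, SE 0.15, adjusted p = 1.33e-05). Ogn, the secreted proteoglycan osteoglycin, was 4.21-fold lower and Clu, the extracellular chaperone clusterin, 3.46-fold lower. Matn2 (3.29-fold), a matrix protein, Slc7a11 (3.29-fold), the cystine and glutamate exchanger, and Igfbp5 (3.19-fold), which binds insulin-like growth factors, fell as well. Grm8 (2.79-fold), a glutamate receptor, the noncoding RNA Rian (2.78-fold), Angpt1 (2.71-fold), a ligand of the endothelial receptor Tek, and Pgam2 (2.49-fold), a phosphoglycerate mutase, completed the 12. The calls of Slc6a15, Thbs1, Ogn and Rian were lost with the macrophage score as a covariate (adjusted p = 0.0758, 0.0583, 0.0666 and 0.0990). With it their changes were 1.65, 0.98, −2.10 and −1.57, against 2.28, 1.68, −2.07 and −1.47 without it.

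**Figure D1:**
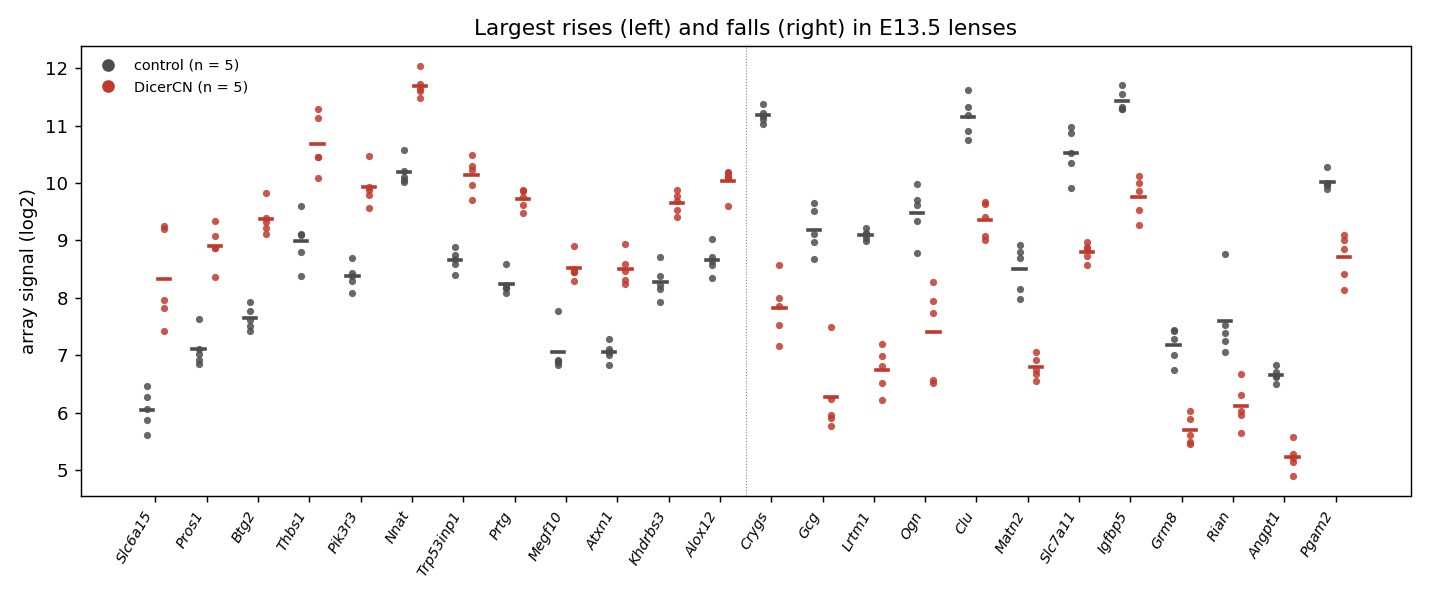
Log2 array signal (vertical axis) of the 12 genes with the largest rises (left of the dotted line) and the 12 with the largest falls (right), 1 point per array, control arrays in grey and DicerCN arrays in red, 5 each, with bars at the group means. In each gene the points of the groups do not overlap, and in Crygs the mean goes from 11.18 to 7.83.

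Of 34 measured reported targets of let-7, 5 rose and 2 fell (9 and 2 adjusted over the list alone). Trim71, which keeps early progenitors undifferentiated, rose by 0.80 (SE 0.10) and Ccnd1, cyclin D1, by 0.84 (SE 0.12), while Myc fell by 1.01 (SE 0.13). The list as a whole was higher (camera adjusted p = 0.00245), and the call was lost with an estimated correlation (adjusted p = 0.257). Of 22 targets of the miR-17 family, 6 rose and 0 fell (9 and 0 adjusted over the list alone), among them Phlpp2, a phosphatase of Akt, by 0.82, Mink1 by 0.62 and Bcl2l11, the pro-apoptotic protein Bim, by 0.49. That list was higher at an adjusted p of 0.000158, with an adjusted p = 0.287 with an estimated correlation. Among 15 targets of miR-204, a microRNA abundant in lens and retina, 4 rose and 0 fell, the same numbers adjusted over the list alone: Rab22a by 0.88, Sox4 by 0.75, Meis2 by 0.42 and Tcf12 by 0.37 (list adjusted p = 0.00165, and adjusted p = 0.257 with an estimated correlation). Among 18 targets of miR-200 and miR-205, 4 rose and 0 fell (5 and 0 adjusted over the list alone), led by Fn1, fibronectin, by 0.91 and Ypel2 by 0.55. Zeb1 and Zeb2, named here after their values were seen, changed by 0.17 (SE 0.11) and −0.07 (SE 0.09) and did not pass the test. This list had an adjusted p of 0.000999, with an adjusted p = 0.287 with an estimated correlation. Targets of miR-124, a microRNA of neurons, shifted too (adjusted p = 0.0117, and adjusted p = 0.291 with an estimated correlation), although only Ptbp1 of 18 rose, by 0.33 (2 adjusted over the list alone). The call of Ptbp1 was lost when any 1 of 6 arrays was left out, at adjusted p between 0.0542 and 0.0799. With the macrophage score as a covariate, the calls of the miR-204, miR-200 with miR-205, and miR-124 lists ended (adjusted p = 0.0836, 0.145 and 0.593). Their means went from 0.25, 0.21 and 0.11 to 0.19, 0.11 and 0.025. The calls of Mink1, Bcl2l11, Sox4, Meis2, Tcf12, Fn1, Ypel2 and Ptbp1 ended with it as well (0.0628 to 0.270). The Tcf12 call was also lost with the replicate number as a block (0.0521) and with the retina score (0.0598). That of Ptbp1 was lost with the retina score (0.0943), over the mean of its probe sets (0.0968) and without control replicate 4 and DicerCN replicate 5 (0.0861).

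Of 21 genes of the microRNA pathway, 4 rose and 1 fell (7 and 2 adjusted over the list alone). Ago1 and Ago2, Argonaute proteins that bind mature microRNAs, rose by 0.79 (SE 0.08, adjusted p = 0.000163) and 0.53 (SE 0.11, adjusted p = 0.0133). Tnrc6a, a partner of Argonautes, rose by 0.43, and Ago3 by 0.40. Dis3l2, an exonuclease that degrades let-7 precursors, fell by 0.32 and is named after its value was seen. The calls of Tnrc6a without control replicate 1 (adjusted p = 0.0610) and of Ago3 without any 1 of 8 arrays (0.0570 to 0.105) were lost. Ago2, Tnrc6a and Ago3 did not pass with the macrophage score as a covariate (0.193, 0.273 and 0.268). Ago3 did not pass either with the Y-linked (0.0630) or muscle (0.0783) covariate or without control replicate 4 and DicerCN replicate 5 (0.0527). The list's shift was near the threshold (adjusted p = 0.0470, and adjusted p = 0.480 with an estimated correlation), and it was lost without control replicate 2, 4 or 5 or DicerCN replicate 1 or 5 (0.0619 to 0.111). The retina (0.143), muscle (0.116) and Y-linked (0.0834) covariates also ended it. So did leaving out the genes of lowest signal (0.0640), taking the mean of probe sets (0.0561) and leaving out control replicate 4 with DicerCN replicate 5 (0.224).

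Of 29 p53 targets, 11 rose and 0 fell (12 and 0 adjusted over the list alone). Besides Btg2 (rise of 1.72, SE 0.13, adjusted p = 4.59e-05) and Trp53inp1 (1.48, SE 0.14, adjusted p = 0.000144), Tnfrsf10b, a death receptor, rose by 0.96 (SE 0.16) and Ddit4l by 0.71 (SE 0.11). Mdm2, the ubiquitin ligase of p53 and itself a classical target, is named after its value was seen and stood at −0.09 (SE 0.07, adjusted p = 0.566). The list was higher in all 5 DicerCN arrays (score 0.31 ± 0.07 against control SD 0.06, n = 5 each, exact permutation p = 0.00794, the smallest possible). Its camera adjusted p was 4.07e-06, and its adjusted p = 0.223 with an estimated correlation was the smallest of all lists. Of 25 apoptosis effectors, 3 rose and 1 fell (4 and 1 adjusted over the list alone): Mcl1, an inhibitor of cell death, by 0.50, Bcl2l11 by 0.49 and Apaf1, a caspase activator, by 0.37, while Bid, a pro-apoptotic protein, fell by 0.63. The call of Apaf1 was lost without control replicate 1 (adjusted p = 0.0566), and the calls of Tnfrsf10b, Ddit4l, Mcl1, Bcl2l11 and Apaf1 with the macrophage covariate (0.0722 to 0.242). This list was not shifted (adjusted p = 0.221), with a mean of 0.06 and a median of −0.0035.

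Of 29 genes of G1/S and DNA replication and of 29 of G2/M and mitosis, 0 rose and 0 fell, also when adjusted over the list alone. E2f1, a transcription factor of S-phase entry, stood at 0.42 (SE 0.14, adjusted p = 0.104, and 0.0487 without DicerCN replicate 1), and Kif23, a kinesin of cytokinesis, at 0.31 (SE 0.10, adjusted p = 0.0778). Camera placed both lists higher (adjusted p = 0.00626 and 0.0275), with adjusted p = 0.480 and adjusted p = 0.589 with an estimated correlation. DicerCN replicate 5, which had the highest neural retina score, also had the highest scores in both (0.31 and 0.41). Without it the adjusted p were 0.111 and 0.588, and with the retina score as a covariate both were 0.578. The G1/S call was also lost without control replicate 5 or DicerCN replicate 4, and the G2/M call without control replicate 1, 4 or 5 or DicerCN replicate 4. Without control replicate 4 and DicerCN replicate 5 both were lost (0.221 and 0.957), with the G2/M mean at −0.014. The Y-linked (0.0855) and muscle (0.117) covariates ended the G2/M call. Among 12 cyclin-dependent kinase inhibitors and related genes, 1 rose and 1 fell, the same numbers adjusted over the list alone, with no shift (adjusted p = 0.763). These were Rbl2 (0.50), a pocket protein, and Cdkn1c (−0.46), an inhibitor expressed as fibre cells leave the cycle, and each call was lost without any 1 of 8 arrays (adjusted p up to 0.116 and 0.0652). Rbl2 also lost it with the macrophage (0.437), muscle (0.0855) and Y-linked (0.0683) covariates and without control replicate 4 and DicerCN replicate 5 (0.0836). Cdkn1c lost it with the macrophage (0.158), retina (0.102) and muscle (0.0564) covariates, after quantile normalization (0.0788) and without those arrays (0.107).

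Of 15 measured crystallins, the bulk proteins of the lens, 0 rose and 6 fell (0 and 8 adjusted over the list alone), and 14 of 15 were lower. Control means of 12 of them lay in the top percent of all values, and whether falls are understated at such signals was not tested. After Crygs, Crygn fell by 1.05 (SE 0.19), Cryba2 by 0.76 (SE 0.11) and Crybb2 by 0.36 (SE 0.07). The list was lower at an adjusted p of 2.7e-07, with an adjusted p = 0.287 with an estimated correlation, and its score was below all controls in all 5 DicerCN arrays (−0.50 ± 0.15, SD, n = 5, exact permutation p = 0.00794). Among 31 lens fibre genes, 2 rose and 7 fell (3 and 10 adjusted over the list alone): Grifin, a lens galectin, fell by 0.64, Nrcam, an adhesion protein, by 0.69, Lctl by 0.60 and Birc7 by 0.59. The fibre list was lower (adjusted p = 0.00402), with an adjusted p = 0.480 with an estimated correlation, and the retina score as a covariate ended its call (adjusted p = 0.126). With the retina score its mean was −0.079 against −0.17 without it. Of 26 lens epithelium genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone). Eya1, a transcriptional coactivator of eye development, rose by 0.56, Tfap2b by 0.68 and Meis2 by 0.42, and Cdh1, E-cadherin, fell by 0.79 (SE 0.15). That list was higher (adjusted p = 0.0215, and adjusted p = 0.287 with an estimated correlation), and its call was lost without control replicate 5 (0.0517) or DicerCN replicate 3 (0.0703) and with the macrophage score as a covariate (0.413). With the macrophage score its mean was 0.055 against 0.18 without it. Crygn, Crybb2, Nrcam, Lctl, Birc7, Eya1, Tfap2b, Meis2 and Cdh1 did not pass with that covariate (0.0602 to 0.334). Of 20 lens transcription factors, 2 rose and 0 fell (6 and 2 adjusted over the list alone), the pair Eya1 and Meis2, and the list was not shifted (adjusted p = 0.0693). Without control replicate 1 or 3 or DicerCN replicate 4 or 5 it was (0.0329 to 0.0393), as it was after quantile normalization (0.0253) and with the retina covariate (0.0143). Pitx3, mutated in mice with small or absent lenses, stood at −0.40 (SE 0.12, adjusted p = 0.0611, and 0.0439 and 0.0437 without DicerCN replicate 2 or 3, and 0.0362 with array weights) and Gata3 at 0.50 (SE 0.14, adjusted p = 0.0618, and 0.0410 and 0.0285 without DicerCN replicate 4 or 5). Gata3 also passed after quantile normalization (0.0497), with array weights (0.0426), with the retina covariate (0.0192) and without control replicate 4 and DicerCN replicate 5 (0.0423).

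Of 20 genes of cholesterol synthesis, 0 rose and 7 fell (0 and 12 adjusted over the list alone). Pmvk, Fdps and Mvk, enzymes of the mevalonate branch, fell by 0.57 (SE 0.08), 0.61 (SE 0.09) and 0.41 (SE 0.09), and Tm7sf2, a sterol reductase, by 0.63 (SE 0.11). The list was lower at an adjusted p of 1.08e-07, with an adjusted p = 0.287 with an estimated correlation. Of 21 genes of glycolysis and hypoxia, 1 rose and 3 fell (1 and 8 adjusted over the list alone), and the list was lower (adjusted p = 0.000305, and adjusted p = 0.291 with an estimated correlation). Ndrg1, a gene induced by hypoxia, fell by 0.62, P4ha1, a prolyl hydroxylase of collagen, by 0.80 and Aldoc, an aldolase, by 0.78, while Egln3, an oxygen sensor induced by hypoxia, rose by 0.60. The call of Aldoc was lost without control replicate 1 or 3 or DicerCN replicate 4 (adjusted p up to 0.0610) and with the retina covariate (0.0748), which also ended that of P4ha1 (0.0559). Of 20 genes of heat shock and oxidative stress, 2 rose and 1 fell, the same numbers adjusted over the list alone, with no shift (adjusted p = 0.315). The metallothionein gene Mt1 rose by 0.81 and Mt2 by 0.68, next to the fall of Slc7a11 by 1.72, and the Mt2 call was lost without control replicate 2 (adjusted p = 0.0515). Of 20 genes of the unfolded protein response, 1 rose, also adjusted over the list alone, namely Dnajb9, an endoplasmic reticulum chaperone, by 0.59 (list adjusted p = 0.372). Among 18 interferon response genes, 0 rose and 0 fell in limma, also when adjusted over the list alone (list adjusted p = 0.179). Only 2 of the 18 lay above the median level in controls, so most were measured at low signal. Among these metabolic and stress genes, Fdps, Tm7sf2, Mvk, P4ha1, Aldoc, Egln3, Mt1, Mt2 and Dnajb9 did not pass with the macrophage covariate (0.0754 to 0.426).

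**Figure D2:**
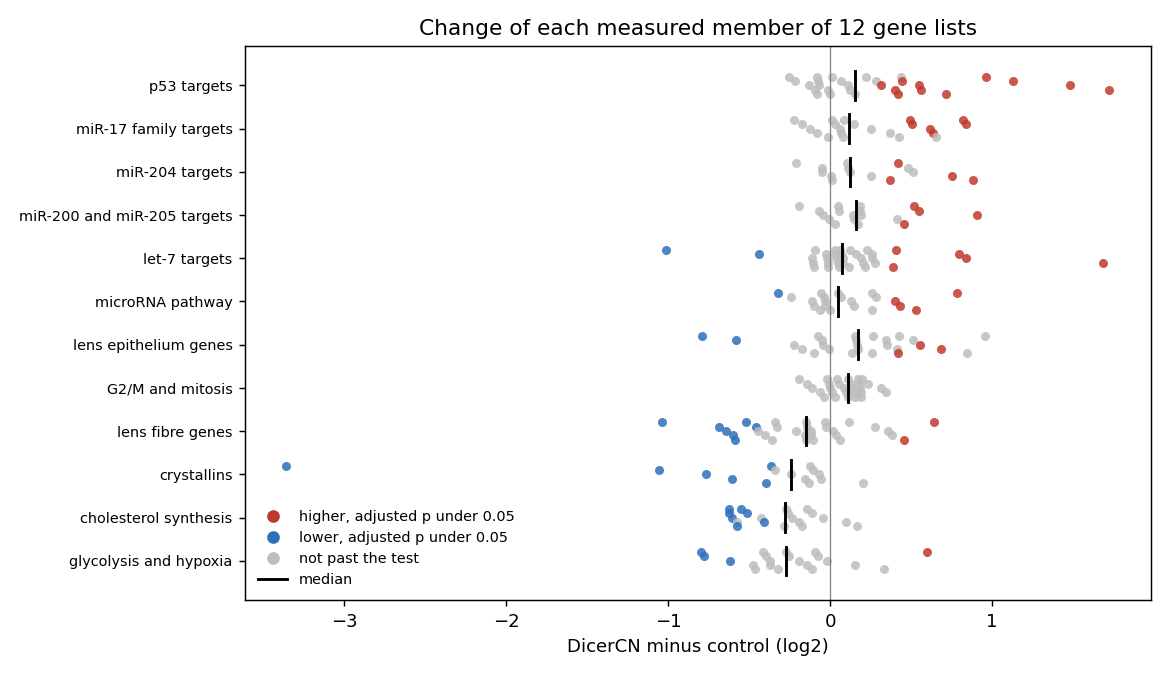
Change of each measured member of 12 gene lists, DicerCN minus control on the log2 scale (horizontal axis), 1 point per gene, with a black bar at the list's median. Red points rose and blue points fell at an adjusted p under 0.05, and grey points did not pass. Of the crystallins 6 are blue and 0 red, and of the p53 targets 11 are red and 0 blue.

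Of 29 Wnt pathway genes, 1 rose and 2 fell, the same numbers adjusted over the list alone: the Wnt receptor Fzd1 rose by 0.82 (SE 0.09, adjusted p = 0.000277), Fzd7 fell by 0.73 (SE 0.07, adjusted p = 0.000153) and Fzd3 by 0.40. Of 23 genes of the FGF and ERK pathway, 1 rose and 1 fell (2 and 2 adjusted over the list alone): Fgfr2, a receptor of fibroblast growth factors, fell by 0.65 (SE 0.09), and Dusp6, a phosphatase of ERK, rose by 0.44. Of 28 genes of the BMP and TGF-beta pathway, 2 rose and 2 fell (3 and 2 adjusted over the list alone), with Id2 lower by 0.79 on the log2 scale, Tgfb2 lower by 0.51, Smad7, an inhibitory Smad, higher by 0.49 and Ccn2, a matricellular growth factor, higher by 0.38. When 1 array was left out, the calls of Fzd3 (4 arrays), Dusp6 (7 arrays), Ccn2 (7 arrays) and Smad7 (control replicate 1) were lost, at adjusted p up to 0.0838. The macrophage covariate ended these 4 calls and that of Tgfb2 (0.101 to 0.594). With it the changes were −0.25 for Fzd3, 0.16 for Dusp6, 0.37 for Ccn2, 0.39 for Smad7 and −0.43 for Tgfb2. The muscle covariate ended those of Dusp6 (0.0557) and Ccn2 (0.0636), the Y-linked covariate that of Ccn2 (0.0515), and leaving out control replicate 4 with DicerCN replicate 5 that of Smad7 (0.0528). None of these 3 lists was shifted by camera (adjusted p = 0.536, 0.167 and 0.206). The Notch list was higher (adjusted p = 0.00245, and adjusted p = 0.328 with an estimated correlation), with 1 of 20 genes up, also adjusted over the list alone: Lfng, a glycosyltransferase that modifies Notch, rose by 0.40, a call lost without any 1 of 5 arrays (adjusted p up to 0.0641) and with the replicate number as a block (0.0569). The list's call ended with the macrophage score as a covariate (adjusted p = 0.149). So did the calls of Lfng (0.259), and of Cdh1 (0.163), Fn1 (0.176) and Tnc (0.232) in the lists that follow. Of 23 epithelial junction genes, 0 rose and 1, Cdh1, fell (2 and 1 adjusted over the list alone; list adjusted p = 0.188). The extracellular matrix list was higher (adjusted p = 0.00478, and adjusted p = 0.480 with an estimated correlation), with 2 of 28 genes up (4 adjusted over the list alone), Fn1 and Tnc, tenascin C, the latter by 1.32 (SE 0.26). Its call was lost without DicerCN replicate 3 (adjusted p = 0.0703), an array with high scores for matrix (0.72), macrophage (1.03) and endothelial genes (0.69), and its mean turned to −0.14 with the macrophage score as a covariate (adjusted p = 0.245).

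Of 15 imprinted growth genes, 2 rose and 5 fell (2 and 7 adjusted over the list alone), and the list was not shifted (adjusted p = 0.0693, and 0.0383 and 0.0346 without control replicate 1 or 5). It was lower with the replicate number as a block (0.0480) and with the macrophage covariate (mean −0.38 against −0.22, adjusted p = 0.0101). Igf2r, the receptor that clears insulin-like growth factor 2, rose by 0.47, and Peg3 fell by 0.66, Zim1 by 0.82 and Rian by 1.47. Of 20 noncoding and coding hosts of microRNA precursors, 0 rose and 3 fell (1 and 3 adjusted over the list alone; list adjusted p = 0.210): Rian, Meg3 (fell by 0.94, SE 0.20) and Copz2 (fell by 0.65, SE 0.09). Igf2r, Peg3, Zim1, Rian and Meg3 did not pass with the macrophage covariate (0.0915 to 0.182), nor did Meg3 without control replicate 4 and DicerCN replicate 5 (0.0548). In both lists control replicate 4, the array with muscle transcripts, had the highest score of all arrays (0.51 and 0.11), and Rian stood at 8.77 in it and at 7.05 to 7.53 in the other controls.

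Markers of other cell types differed between single arrays. All 19 measured macrophage genes were higher in DicerCN lenses, and 3 rose (12 adjusted over the list alone): Csf1r by 0.86 (SE 0.17), Cx3cr1 by 0.73 (SE 0.15) and Ctss, a lysosomal protease, by 0.73 (SE 0.17), the last a call lost without control replicate 1 or 5 or DicerCN replicate 4 (adjusted p up to 0.0603). Macrophage scores were 0.82, 0.19, 1.03, 0.70 and 0.17 in DicerCN replicates 1 to 5, against a highest control score of 0.32 in replicate 4 (camera adjusted p = 3.01e-09, adjusted p = 0.291 with an estimated correlation, exact permutation p = 0.0397). No neural retina gene of 19 passed, also when adjusted over the list alone, but all 19 were higher, with scores of −0.21, 0.44, 0.06, 0.67 and 1.83 in DicerCN replicates 1 to 5 and a highest control score of 0.40 (camera adjusted p = 0.000984, adjusted p = 0.480 with an estimated correlation, exact permutation p = 0.103). Without DicerCN replicate 5 the retina list was no longer shifted (adjusted p = 0.0604), nor was it without that array and control replicate 4 (0.171). In the pigment epithelium list 0 of 14 genes rose or fell (4 up and 1 down adjusted over the list alone; camera adjusted p = 0.00183, adjusted p = 0.440 with an estimated correlation), with the highest scores in DicerCN replicates 4 (1.22), 5 (0.85) and 1 (0.62). Pmel, a melanosome protein, stood at 1.47 (SE 0.43, adjusted p = 0.0609, and 0.0175 and 0.0311 without DicerCN replicate 2 or 3, 0.0377 with array weights and 0.0467 with the replicate block). Endothelial and erythroid lists were higher by camera (adjusted p = 0.00493 and 0.0217), with adjusted p = 0.537 and adjusted p = 0.480 with an estimated correlation, and 0 of 20 and 0 of 11 genes rose or fell, also when adjusted over the lists alone. The endothelial call was lost without DicerCN replicate 1 (0.0789) or 3 (0.117), and the erythroid call without control replicate 2 or 4 or DicerCN replicate 1 or 5 (0.0566 to 0.136). The latter was also lost with the retina (0.134) and muscle (0.122) covariates, without the genes of lowest signal (0.0570) and without control replicate 4 and DicerCN replicate 5 (0.360). With the macrophage score as a covariate the endothelial mean turned from 0.22 to −0.36 (camera adjusted p = 4.26e-07 with the preset correlation). That fit was not repeated with an estimated correlation. The endothelial genes had a mean correlation of 0.819 within groups, so this adjusted p overstates the evidence.

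Striated muscle genes were lower by camera (adjusted p = 0.0149, and adjusted p = 0.567 with an estimated correlation), with 0 of 16 rising or falling, also when adjusted over the list alone. That shift was due to control replicate 4 alone, with a score of 2.65 against −0.85 to −0.50 in the other controls. Myh3, an embryonic myosin heavy chain, had a log2 signal of 11.81 there and of 6.06 to 6.54 in the other controls, and without that array the list's mean was 0.02 (adjusted p = 0.615). The call was also lost without the genes of lowest signal (0.0842), with the retina covariate (0.0979) and without control replicate 4 and DicerCN replicate 5 (0.810). Periocular mesenchyme was not shifted (1 of 21 rose, 2 fell, the same numbers adjusted over the list alone, adjusted p = 0.0693), and it became so, upward, without control replicate 4 (adjusted p = 0.00127) or DicerCN replicate 2 (0.0378) or 5 (0.0136). The block (0.0451), the Y-linked (0.0206), retina (0.00675) and muscle (0.00182) covariates had the same effect. So had leaving out control replicate 4 with DicerCN replicate 5 (3.70e-05). With the macrophage covariate the mean turned to −0.25 (0.199). In it Ogn fell, Prrx2 rose by 0.56 and Pdgfra fell by 0.58, and the last 2 calls were lost without any 1 of 5 and of 7 arrays (adjusted p up to 0.0657 and 0.108). They were lost with the macrophage covariate as well (0.208 and 0.334), that of Prrx2 also with the block (0.0682). The Pdgfra call was lost after quantile normalization (0.0577), with the Y-linked (0.0522), retina (0.148) and muscle (0.0564) covariates and without control replicate 4 and DicerCN replicate 5 (0.0911). Of 21 genes of surface ectoderm and cornea, 0 rose and 1 fell (1 and 1 adjusted over the list alone), the keratin gene Krt4 by 0.31, and this list was not shifted (adjusted p = 0.536). Only 1 of the 21 lay above the median level in controls. The Krt4 call was lost without any 1 of 9 arrays (adjusted p up to 0.133), with the block (0.113) and with the Y-linked (0.0751), retina (0.0837) and macrophage (0.474) covariates.

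**Figure D3:**
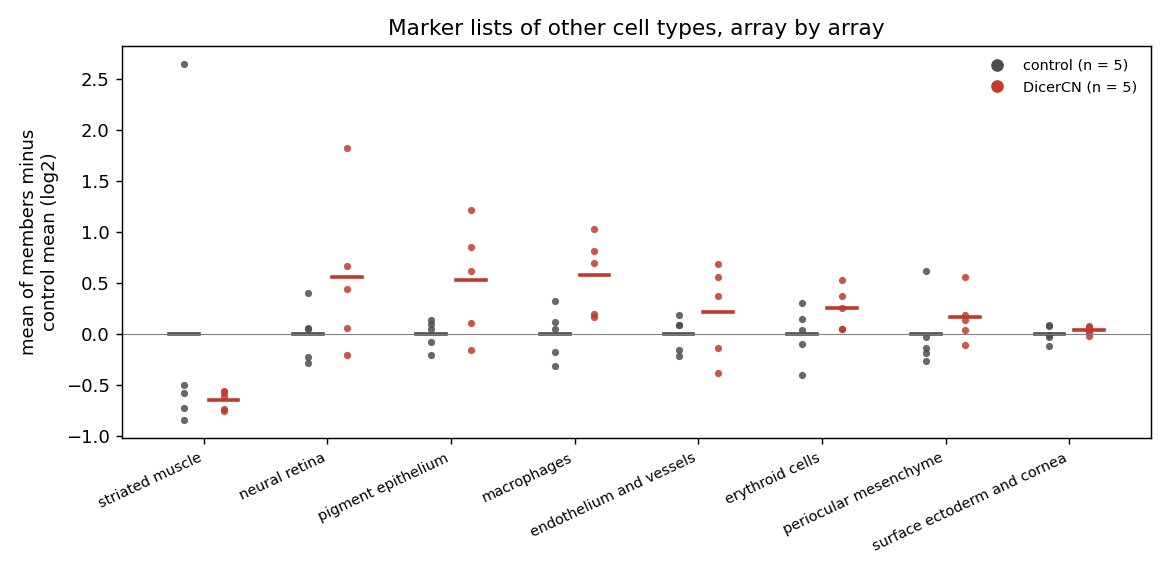
Scores of 8 marker lists of other cell types (mean log2 signal of the members minus the control mean, vertical axis), 1 point per array, 5 control arrays in grey and 5 DicerCN arrays in red, with bars at the group means. A single control array lies at 2.65 for striated muscle, and a single DicerCN array at 1.83 for neural retina.

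By camera with the preset correlation, 22 of 36 lists were shifted, 17 up and 5 down. Lists share genes, so their shifts are not separate results. Also in another list were 17 of 20 lens transcription factors, 16 of 26 lens epithelium genes, 10 of 22 miR-17 targets and 10 of 28 matrix genes. With estimated correlations 0 of 36 passed (smallest adjusted p = 0.223, and 4 lists at an unadjusted p under 0.05), and by fry 10 did: the targets of let-7, miR-17, miR-204, miR-200 with miR-205, and miR-124, p53 targets, crystallins, lens epithelium, glycolysis and hypoxia, and cholesterol synthesis. Without control replicate 4 and DicerCN replicate 5, 1154 genes differed (475 higher and 679 lower), 954 of them among the 1303, and 17 lists were shifted. The count of genes was 784 without control replicate 1, 865 without control replicate 2 and 241 with the macrophage score as a covariate, and 504 genes were lower without control replicate 3. Of the 93 named genes that passed the test, 75 passed it with each array left out in turn, and 36 under every setting in which all genes were tested at the same threshold. The other 57 lost their call with the macrophage covariate, with which the median SE of the 1303 genes was 0.137 against 0.0981 and all kept their direction. Controls carried no Cre, so presence of Cre and loss of Dicer go together in this comparison.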

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

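The tests of the retina, pigment and macrophage genes in this part were chosen after the results had been seen. Neural retina, pigment epithelium and macrophage lists were higher in DicerCN samples, by camera with its preset correlation and not with an estimated one (adjusted p = 0.480, 0.440 and 0.291 with an estimated correlation) nor by fry (0.329, 0.167 and 0.0629). Among the most abundant markers, the retina gene Rax reached 9.76 in DicerCN samples and 8.19 in control samples, Pmel 9.73 and 7.33, and the macrophage gene Laptm5 9.07 and 7.65 (highest log2 signals). Of the retina list 1 of 19 genes is in another list and 7 lie above the median level in controls, of the pigment list 1 and 6 of 14, and of the macrophage list 0 and 8 of 19. Retina carried over by dissection as the whole source of the 1303 genes is argued against, since 848 of them (65.1%) were also called with the retina score as a covariate. Retina tissue carried over with some lenses may account for the retina list itself. Its genes moved together within groups (mean correlation 0.685, against at most 0.133 in 1000 matched random lists). Such co-movement cannot tell carried-over tissue from regulation, since crystallins, genes of the lens itself, had 0.465, above 99.5% of matched random lists. The p53 targets had 0.050, above 95.8% of theirs. A retina score above all controls was seen in 3 of 5 DicerCN arrays and not in every one. DicerCN replicates 1 and 3 lay within the control range (−0.21 and 0.06), and whether they hold a smaller rise stays open.

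With the macrophage score as a covariate, 241 genes were called, 222 of them among the 1303, and all 1303 kept their direction. Their median change was 0.45 against 0.48 without it, and their median SE rose from 0.0981 to 0.137, since the score and the group are correlated (0.709). Macrophage genes also moved together within groups (mean correlation 0.684, against at most 0.172 in matched random lists), and whether the cells came from the lens surroundings or differ with the genotype was not tested.

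Single arrays stood far from the 4 others of their group in 24 of 378 tested values (17 genes and 7 lists), where chance gives about 18.9. The measure is the gap to the nearest array over the range of the group, with 0.71 as the limit. Control replicate 4 was such an array for Megf10 (0.919, signal 7.77), Rian (0.725, signal 8.77), Mylpf (0.873, signal 8.55), Tnni1 (0.863, signal 9.83) and Myh3 (0.916, signal 11.81), and for the lists of striated muscle (0.901), extracellular matrix (0.752), periocular mesenchyme (0.727) and imprinted growth genes (0.711). Its most abundant muscle transcript, Actc1, stood at 12.86 against a lowest control value of 7.39, and of the 16 muscle genes 0 are in another list and 7 lie above the median level in controls. In control replicate 2, Pgam2 (0.728) and Crygn (0.797) were high and Igf2r (0.876) was low. Ccn2 was high in control replicate 1 (0.791) and Prtg in control replicate 5 (0.727). In DicerCN replicate 1, Bcl2l11 (0.754), Gadd45g (0.764) and the list of cyclin-dependent kinase inhibitors (0.839) were high and the imprinted list (0.795) was low. Without that array Gadd45g, a gene induced by growth arrest, passed the test (fell by 0.61, adjusted p = 0.00641). Gcg was high in DicerCN replicate 2 (0.725, signal 7.49 against at most 6.25 in the others), and Tnfrsf10b (0.752) and Egln3 (0.730) were high in DicerCN replicate 3. In DicerCN replicate 5, Ccnd1 was high (0.779) and Alox12 (0.864) and the p53 list (0.836, score 0.19 against 0.33 to 0.36) were low.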

How the results depend on the processing

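The neural retina, macrophage and muscle covariates and the fit without control replicate 4 and DicerCN replicate 5 were chosen after the data had been seen. The 1303 genes became 153 (65 higher, 88 lower) with treat at 1.2-fold, 408 (184 and 224) at 1.5-fold or more and 485 (186 and 299) at an adjusted p under 0.01, all of which are stricter criteria. With the macrophage covariate they became 241 (67 and 174), and with the retina covariate 515 were lower. The macrophage covariate raised the SE, and single changes moved as well. Thbs1 went from 1.68 to 0.98 and Rian from −1.47 to −1.57. The other settings with all arrays gave 1014 to 1650 genes: 1350 after quantile normalization, 1292 after median centring, 1650 with array weights, 1199 over all probe sets, 1161 with the Y-linked covariate and 1100 with the replicate number as a block. No pairing by that number was seen, since 2 of 10 arrays correlated best with the array of their own number. Mean correlations were 0.035 for the same number and −0.009 for other numbers, which does not exclude a pairing. Leaving out 1 array gave 784 to 1295 genes, 303 to 503 higher and 481 to 840 lower. Dicer1 stayed between 0.067 and 0.22 in the settings with all arrays and in the fit without both doubtful arrays, and was not called. Of 36 lists, 0 were shifted with estimated correlations and 10 by fry, against 22 with the preset correlation, and 16 to 24 in the other settings. With the macrophage covariate the changes of Cdkn2b (−0.024), Robo4 (−0.063), Sox17 (−0.00093) and Pdgfrb (−0.37) turned negative, none of them called. So did the means of the Wnt (−0.0020), BMP and TGF-beta (−0.066), extracellular matrix (−0.14), unfolded protein response (−0.040), heat shock and oxidative stress (−0.045), periocular mesenchyme (−0.25) and endothelium (−0.36) lists. The same covariate made the means of other lists larger. Neural retina went from 0.56 to 1.14 and striated muscle, a shift due to control replicate 4 alone, from −0.64 to −1.27. Crystallins went from −0.50 to −0.61 and lens fibre genes from −0.17 to −0.29. The list of cyclin-dependent kinase inhibitors turned to 0.017 after quantile normalization and 0.030 with the retina covariate, and G2/M and mitosis to −0.034 with the retina covariate and −0.014 without both doubtful arrays. With 1 array left out, the means of 4 lists crossed 0: cyclin-dependent kinase inhibitors (−0.046 to 0.021), unfolded protein response (−0.0036 to 0.083), heat shock and oxidative stress (−0.016 to 0.041) and striated muscle (−0.86 to 0.017). Apart from the stricter criteria, the cause was not tested. Over the 1303 genes the macrophage covariate took the median change from 0.48 to 0.45 and the median SE from 0.0981 to 0.137. As a set they thus lost precision more than size. For single genes a larger SE and smaller changes were not told apart. No alternative pseudocount was run. Of the called genes, 49 had a mean in the lowest 33.3% of signals, where a change is hardest to tell from background.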

Other observations

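The gene families in this part were chosen after the main results had been seen, and so were the tests of the interval between Dlk1 and Dio3. Of 11 families taken by symbol, 4 were lower in DicerCN lenses with an estimated correlation. These adjusted p run over the 11 families alone, chosen after the falls had been seen. They cannot be set against those of the 36 lists fixed beforehand, and they do not make the families firmer than those lists. In the respiratory chain 39 of 85 genes fell and 0 rose (median −0.35, adjusted p = 0.0362 with an estimated correlation), among them Ndufb7 of complex I, which fell by 0.69 (SE 0.08), and Atp5e of ATP synthase, which fell by 0.74 (SE 0.08). Of 60 cytosolic ribosomal protein genes 21 fell and 0 rose (median −0.26, adjusted p = 0.0390 with an estimated correlation), with Rpl27 at −0.58 (SE 0.09). Of 77 mitochondrial ribosomal protein genes 22 fell and 0 rose (median −0.26, adjusted p = 0.0362 with an estimated correlation), with Mrpl42 at −0.91 (SE 0.12). Of 19 glutathione transferases, enzymes that conjugate glutathione to reactive compounds, 8 fell and 0 rose (median −0.29, adjusted p = 0.0362 with an estimated correlation), with Gstm1 at −1.02 (SE 0.15) and Gstm7 at −0.81 (SE 0.08). The 4 medians stayed negative after quantile normalization (−0.32, −0.19, −0.25 and −0.28) and median centring, and all 5 DicerCN arrays lay below all controls in each (exact permutation p = 0.00794, the smallest possible). Proteasome subunits (5 of 50 fell, adjusted p = 0.138 with an estimated correlation), amino acid transporters (7 rose and 3 fell of 56, 0.175), aminoacyl-tRNA synthetases (4 of 30 fell, 0.175), Trim genes (4 rose and 2 fell of 59, 0.250), Hox genes (0 of 39, 0.658), Zfp genes (3 rose and 8 fell of 347, 0.707) and potassium channels (7 of 92 fell, 0.739) did not pass. With the preset correlation, camera placed proteasome subunits and aminoacyl-tRNA synthetases lower and amino acid transporters higher (adjusted p = 1.53e-07, 0.000886 and 0.0298). By fry these families (0.0132, 0.0196 and 0.0286) and Trim genes (0.0286) passed as well.

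Control means of 12 of 15 crystallins lay in the top percent of all values. Across the 15, a higher control level went with a smaller fall (Spearman rank correlation 0.49), which did not pass a permutation test (p = 0.0657). Granulocyte genes, chosen after their values were seen, were high in DicerCN replicates 1, 3 and 5. S100a9 had log2 signals of 8.32, 8.99 and 8.11 there, 6.31 and 5.66 in DicerCN replicates 2 and 4 and at most 6.02 in controls (adjusted p = 0.0551), and S100a8 stood at 1.28 (SE 0.54, adjusted p = 0.219). Arrays with Y-linked signal numbered 3 in the control and 2 in the DicerCN group, and 5 genes differed between arrays with and without it.

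Chance as the source of the gene counts is argued against: of 100 splits of the 10 arrays into 5 and 5, only the real 1 gave 1303 genes, 511 higher or 792 lower. The highest other split gave 8 genes, all in 1 direction. With 100 splits the test cannot reach below 1 in 100. Each of the other splits mixes both groups, so that a difference between the groups widens its spread and lowers its count. For the lists, 2 of 100 splits gave 22 or more, the real 1 included, and the other gave 23 lists with the preset correlation and 0 genes, so that a count of lists by itself says little about the groups.

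For cytosolic ribosomal and respiratory chain genes, a fall of all brightly measured genes is argued against, because the median of both families was −0.31 (−0.307) while the lowest medians of equally bright random lists were −0.141 and −0.0839. Scaling differences left between the deposited arrays are argued against too: after quantile normalization the median was −0.257 and both families passed (adjusted p = 0.00904 with an estimated correlation). The ribosomal median went from −0.26 to −0.19 and the respiratory one from −0.35 to −0.32. The method used before deposit is not known, and a further normalization cannot test it. A short gene span as the whole cause is argued against, since 29.0% of the 145 family genes span under 3000 bases. The medians under and over that limit were −0.314 and −0.307. Short mRNAs, whose length was not measured, stay open. Random draws of equally bright other genes of short span had a median change of −0.152, as the mean over the draws. Equally bright random lists of any span stood at −0.036 (ribosomal) and −0.012 (respiratory), so other genes of short span fell in part as well. Adding the macrophage score as a covariate left the median of both families at −0.41 (median SE of a gene 0.132), with an adjusted p = 0.0269 for each with an estimated correlation. With the retina score as a covariate the median was −0.28 (median SE of a gene 0.106 against 0.0951) and the adjusted p were 0.0779 and 0.0625 with an estimated correlation. DicerCN replicates 1 and 3, with retina scores of −0.21 and 0.06, had ribosomal scores of −0.22 and −0.27 and respiratory scores of −0.22 and −0.34, below all controls. An effect of the genotype, in which Dicer and Cre cannot be separated, may add to these and was not tested on its own.

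Between Dlk1 and Dio3, an imprinted interval that holds Meg3, Rian and a large microRNA cluster, 45 of 46 measured genes were lower in DicerCN samples and 6 fell (median −0.40, exact permutation p = 0.00794), although 27 of the 46 lay in the lowest 33.3% of signals. MicroRNA genes made up 40 of the 46, of which 39 were lower and 3 fell. Whether their probe sets read mature microRNAs or longer precursors was not tested, so these values do not give levels of mature microRNAs. Muscle carried over in control replicate 4 as the whole cause is argued against by an exact permutation p of 0.0159 without that array, but the median was then −0.20 instead of −0.40, so a large part of the change goes with that array. This test was put in place of one on that median after the median had been seen to lie at its limit. For the change that remains without control replicate 4, less mesenchyme in DicerCN samples is argued against, since the mesenchyme list was then higher (median 0.385). For the part that goes with that array it stays open. That array had the highest mesenchyme score (0.62), and with all arrays the list was not shifted (camera adjusted p = 0.0693). Of its 21 genes 1 rose and 2 fell, and with the macrophage covariate its mean was −0.25 (adjusted p = 0.199). A wider chromosome segment is argued against, since 40 flanking genes had a median of 0.0203. The 262 microRNA genes elsewhere, which do not bear on the segment, had a median of 0.0034, with the same limit on mature microRNAs. An effect of the genotype, Dicer loss or Cre, stays open and was not tested apart from these.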
